A study of Mus musculus with 21 samples.

How the data were processed

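Expression was measured on Affymetrix arrays that cover the mouse genome, with biotin-labelled cRNA made from total RNA by a 3' in vitro transcription kit, per the labels' protocols. The deposited table holds 1 value per probe set and array for 45101 probe sets and 21 arrays. Its values are on a log2 scale, judged from their range of 3.74 to 15.1, and the authors' method of summarising and normalising them is not given in the sources used here. The quartiles of the arrays were close to one another (25th percentiles 5.90 to 6.09, 75th percentiles 8.18 to 8.56), so the deposited log2 values were used with no further normalization. A fold change from such values can understate true changes of weakly expressed genes, because background signal compresses low values. The number of arrays, 3 per group, limits the precision, and no read depth applies to arrays.

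Groups and replicate numbers were taken from the sample titles. The labels call the samples biological replicates, and whether equal numbers in different groups mark a shared animal, culture or day is not stated. The series text describes the mice as littermates. Whether the 3 MEF cultures of a group came from separate embryos is not stated, so for MEF the p-values measure the spread between these cultures only. The sex markers given below show only that the knockout MEF did not all come from the same embryo.

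Probe sets were named through the platform's probe table. Of the probe sets, 34958 had 1 gene symbol (18194 genes), 932 had several and were not used for genes, and 9211 were not listed and are unnamed here. Symbols were checked through Entrez identifiers against a RefSeq table of assembly GRCm38.p6, which held 34754 of the 34958 probe sets and changed 0 symbols. That table was otherwise used only to find which genes neighbour Terf2ip, and no coordinates are given because the deposited values name no build. Each gene was represented by its probe set with the highest mean over the arrays of the fit, and genes with a mean under the 40th percentile of all probe sets were left out. This left 13275 genes in liver, 12848 in white adipose tissue, 12816 in MEF and 13116 in the tissue interaction. Other probe sets of a gene can differ from the one used. For Terf2ip a second probe set gave -1.03 in liver and 0.28 in adipose tissue, and the weakest one, at 5.64 and 5.55 in knockout and wildtype liver, gave exact p between 0.5 and 1 over the 5 comparisons.

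Each tissue or cell type was fitted on its own with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the 9 MEF arrays in 1 fit, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The difference of the knockout effects between tissues was tested as the interaction of tissue and genotype over 12 arrays. Fold changes are log2 differences with the standard error of the moderated fit. Gene lists, written before the data were examined along with the designs, the alternatives and the rule for named genes, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry (statmod 1.5.0) were run beside it. Of 789 listed genes, 66 had no probe set with a single symbol. Across the 5 comparisons, 4, 8, 10, 7 and 9 of 27, 28, 22, 22 and 22 lists were called in liver, adipose tissue, knockout against wildtype MEF, I312R against wildtype MEF and I312R against knockout MEF. With an estimated correlation 0 were called in each comparison, and 0 by fry's directional test. Fry's test for change in either direction called 2 in adipose tissue (circadian clock, and ovary and uterus genes, adjusted p = 0.015 and 0.012), the extracellular matrix list (adjusted p = 0.013) in I312R against knockout MEF and none in the others. Where a list's median, mean and camera direction differed in sign (5, 4, 2, 8 and 3 lists, in the same order), the list had not been called.

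Named genes were Terf2ip and, per comparison, the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap, or, where fewer than 16 existed, the genes of smallest p up to 16, described as not passing. Up to 4 members with the smallest p were named for lists that passed or are described. For the interaction the same rule was set for 4 genes in each direction, which gave the 1 gene that passed and the 7 of next smallest p. Xist, Y-linked genes and the 3' and 5' control probe sets of Actb and Gapdh served as checks. Single values of Terf2ip were compared by an exact permutation test.

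Pairing by replicate number was checked through the correlation, across genes, of the deviations of equally numbered arrays from their group means. In MEF every pair correlated above 0.1, at 0.39 to 0.54 for knockout and wildtype, 0.72 to 0.79 for I312R and wildtype and 0.24 to 0.47 for I312R and knockout, so the MEF numbers were taken as pairs from the data, not from the labels. In liver (0.08 to 0.55) and adipose tissue (-0.06 to 0.45) they were not. The main MEF fit held no block. Pairs that deviate together make its p-values too large, so its counts at an unadjusted p under 0.05 can lie under the number expected by chance. Levels of the bioB hybridization control followed the number in MEF, at 7.65 to 7.87, 8.15 to 8.21 and 9.62 to 9.88 for numbers 1, 2 and 3, and in liver at 8.41 to 8.68, 8.79 to 8.83 and 9.87 to 10.3.

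The comparisons of I312R and knockout MEF share arrays, so their correlation and covariance are given beside 100 simulations of unchanged groups with the measured spread. Those simulations held no pairing of equally numbered arrays. Genes near Terf2ip were compared with the rest of the genome by Fisher's exact test. The scripts were tested on simulated data with 200 changed genes. Of 100 genes changed by 1 log2 unit, 76 were recovered in liver, 41 in adipose tissue, 41, 52 and 41 in the 3 MEF comparisons (knockout with wildtype, I312R with wildtype, I312R with knockout) and 45 in the interaction. Of 100 genes changed by 2 log2 units, 97, 85, 83, 88, 87 and 85 were recovered in the same order. These simulations drew arrays as independent, without the differences between arrays of a group that run through many genes together. The alternatives tried were another normalization (quantile, or centring on the median), other filters, every probe set apart or the mean of a gene's probe sets, all arrays in 1 fit, an intensity trend with robust eBayes, array weights, the replicate block, each array left out, and a fold threshold. Figures were drawn with matplotlib 3.10.9.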

Results

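RNA of mice and cultured cells with and without Rap1 was measured on 21 single-colour oligonucleotide arrays, in 7 groups of 3 arrays each. Rap1, encoded by Terf2ip, is a protein of the shelterin complex that binds telomeres through Trf2, and the series title names a role of Rap1 in metabolism away from telomeres. Liver and white adipose tissue came from wildtype and Rap1 knockout C57BL/6 mice of 6 to 8 weeks, and the series text describes the mice as female and the fat as intra-abdominal. Mouse embryonic fibroblasts (MEF), primary cells taken from embryos of day 13.5 and immortalised with the SV40 large T antigen, formed a wildtype group, a knockout group, and a knockout group that expressed Rap1 I312R, which carries arginine in place of isoleucine. The sample labels take the wildtype MEF from wildtype embryos, whereas the series text describes knockout MEF given vector, wildtype Rap1 or mutant Rap1, so the origin of the wildtype MEF group was left open here. The deposited values were on a log2 scale between 3.74 and 15.1, with array medians between 6.75 and 6.82, and the 3 arrays per group set the precision of each value.

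Terf2ip was lower in every knockout liver than in every wildtype liver. Its mean was 7.02 ± 0.10 in knockout and 7.84 ± 0.29 in wildtype liver (log2, SD, n = 3), a difference of -0.82, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 arrays allow. In adipose tissue, knockout replicates 1 and 2 read 7.06 and 6.88, below wildtype replicates 1 and 2 at 7.63 and 7.88. The library labelled knockout adipose replicate 3 read 8.49, the highest of the 6, and the library labelled wildtype adipose replicate 3 read 7.11, near the knockout values. The group means were 7.47 ± 0.88 and 7.54 ± 0.39 (exact p = 0.9). Among the MEF, wildtype replicate 1 read 8.12, but the libraries labelled wildtype MEF replicates 2 and 3 read 7.14 and 7.02, within the knockout range of 7.04 to 7.28 or just under it. The I312R MEF read 7.33 ± 0.07. Where the probe sets lie relative to the deleted part and to the introduced sequence is not given in the sources used here, and every direction drawn below from adipose tissue or MEF includes these libraries under their labels.

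**Figure D1:**
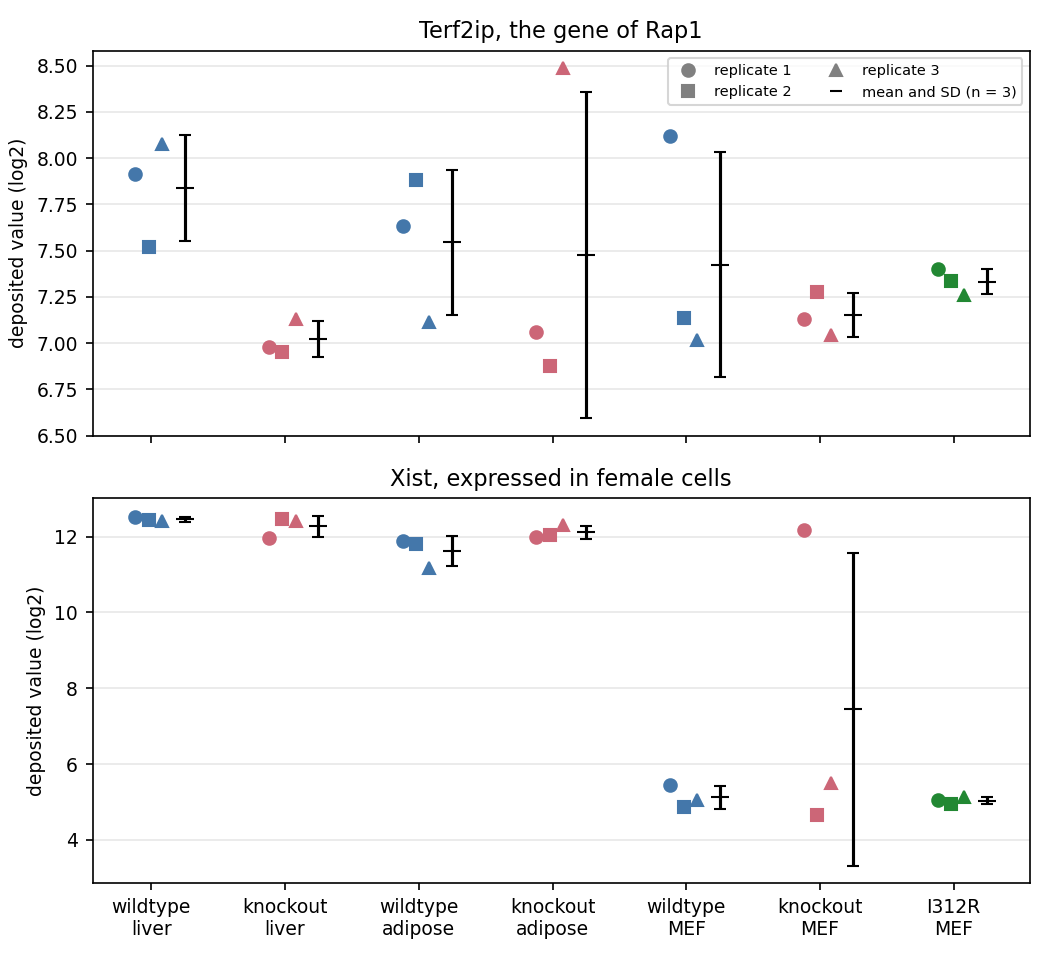
Deposited log2 values of Terf2ip (upper panel) and Xist (lower panel) in each array, by group, with symbols for the replicate number and a bar for the mean and SD of the 3 arrays of a group. The knockout livers lie below the wildtype livers in Terf2ip, the library labelled knockout adipose replicate 3 reads 8.49, and knockout MEF replicate 1 is the only MEF array with a high Xist value, 12.2.

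Xist, the RNA of the inactive X chromosome, was high in all 12 tissue arrays, as in female mice. Knockout MEF replicate 1 had Xist at 12.2 and the Y-linked Eif2s3y at 5.09, whereas the other 8 MEF arrays had Xist between 4.66 and 5.49 and Eif2s3y at 9.32 or above. One of the 3 knockout MEF cultures was thus of the other sex from the rest.

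In the liver, the question was which genes respond to loss of Rap1 in an organ of lipid and glucose metabolism. Genes of lipid synthesis stood slightly higher in knockout liver: 19 of the 25 measured genes of fatty acid and triglyceride synthesis and 15 of the 20 of cholesterol synthesis had positive fold changes, with median log2 fold changes of 0.05 and 0.10. Elovl6, which elongates palmitate, was at 11.26 ± 0.25 in knockout and 10.36 ± 0.35 in wildtype liver, a log2 fold change of 0.89 (SE 0.19). Fasn, the fatty acid synthase, differed by 0.48 (SE 0.13). Genes that male livers normally express more than female livers were also higher, 10 of 13 with a positive fold change and a median of 0.45, among them the steroid dehydrogenase gene Hsd3b5 at 2.33 (SE 0.76). Genes of the unfolded protein and amino acid response were higher in 16 of 21, among them the endoplasmic reticulum chaperone gene Hyou1 at 0.81 (SE 0.30) and Creld2 at 1.09 (SE 0.41), which were 0.40 and 0.50 without knockout liver replicate 3. Hsd3b5 was 1.53 without knockout liver replicate 1.

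The limma test called all 4 of these lists in liver with camera's preset correlation, at adjusted p = 0.00032 for fatty acid and triglyceride synthesis, 0.0015 for cholesterol synthesis, 2.0e-05 for male-biased genes and 4.6e-05 for the unfolded protein response. None held with an estimated correlation: adjusted p = 0.86 with an estimated correlation for each of the 4. Adjusted over the list alone, Elovl6 (adjusted p = 0.026) and Fasn (adjusted p = 0.049) passed in the fatty acid list, and 0 genes passed in the other 3. The male-biased list rested on knockout liver replicate 1, whose list mean lay 1.25 above the wildtype mean against 0.33 and 0.40 in the other 2 knockouts, and its call ended without that array (adjusted p = 0.085, mean log2 fold change 0.39). Female-biased genes, not called with all 6 arrays and the main settings, had list means of 9.75 ± 0.74 in knockout and 9.99 ± 0.03 in wildtype liver. Camera called them as lower with all 21 arrays in 1 fit (mean log2 fold change -0.36, adjusted p = 0.0028). It also did so with every probe set tested separately (-0.23, adjusted p = 0.027). Their mean log2 fold change was 0.21 without knockout replicate 1 (camera adjusted p = 0.027) and -0.49 without knockout replicate 2 (adjusted p = 0.046). The call for fatty acid synthesis ended without knockout liver replicate 2 (adjusted p = 0.15), and that for cholesterol synthesis without wildtype liver replicate 1 (adjusted p = 0.26). The mean of the unfolded protein response list, 0.23 with all arrays, was 0.09 without knockout liver replicate 3 and 0.38 without knockout liver replicate 2, and its call held in both. With all 21 arrays in 1 fit the cholesterol call ended (adjusted p = 0.38). The 53 respiratory chain genes were lower in 47 by a median of -0.05 (adjusted p = 0.056, or 0.047 with the replicate block and 0.85 with the block and an estimated correlation), and camera called none of the other lists in liver with all 6 arrays and these settings. Under 16 alternatives it called 4 to 10 lists, the most with every probe set tested separately and 9 without wildtype liver replicate 3, and the respiratory chain was called in 7 of the 16.

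No single gene of the liver passed. Of 13275 genes tested, 0 had an adjusted p under 0.05 in limma, the smallest adjusted p was 0.999, and 316 had an unadjusted p under 0.05 (125 higher, 191 lower) where 664 would be expected by chance. After quantile normalization these were 432 (243 higher, 189 lower), so no prevailing direction was read from them, and without single arrays 154 to 552. With the replicate block they were 829 (367 higher, 462 lower), above the number expected by chance. The smallest adjusted p in limma was then 0.20, and 0 genes passed. The 16 genes with the smallest p, all outside the threshold, held Terf2ip, the organic anion transporter gene Slc22a7 at 1.16 (SE 0.19), Aacs, which activates acetoacetate for lipid synthesis, at 0.79 (SE 0.13), the growth factor receptor gene Egfr at 0.95 (SE 0.17) and the urinary protein gene Mup10 at 0.88 (SE 0.19). The leptin receptor gene Lepr, at -0.98 (SE 0.22), the glucose transporter gene Slc2a1, at -0.55 (SE 0.13), Mid1, at -1.09 (SE 0.25), Etnppl, at -0.88 (SE 0.20), and the actin gene Actg1, at -0.55 (SE 0.12), were lower. Elovl6, Ighm, Cela1, Tm4sf1, Prelid2 and Cirbp made up the rest, between -0.71 and 0.89. In 865 genes (6.52%) the 3 values of each group did not overlap, where chance gives 10%.

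In white adipose tissue, the differences between the labelled groups were larger and fell into cell type and mitochondrial programmes. Brown-fat genes were lower in all 15 measured members in the knockout libraries, with a median log2 fold change of -2.77. Ucp1, the uncoupling protein of heat-producing fat, differed by -5.02 (SE 1.26), Cidea by -4.43 (SE 0.95), Otop1 by -4.10 (SE 1.07) and Cox7a1 by -3.68 (SE 1.01). Mitochondrial respiratory chain genes were lower in 50 of 53 (median -0.57; Ndufa10 at -1.01, SE 0.30), as were 33 of 38 genes of fatty acid oxidation (median -0.65; Ppara, the fatty acid-sensing receptor, at -2.77, SE 0.81) and 15 of 16 glycolysis genes (median -0.50; Pkm at -1.27, SE 0.49). Fatty acid and triglyceride synthesis genes were lower in 19 of 25 (median -0.18; Agpat2 at -1.01, SE 0.25, and Acly, ATP citrate lyase, at -0.55, SE 0.20).

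Other programmes were higher in the knockout adipose libraries. Mesothelial genes, which mark the lining of the abdominal cavity, were higher in 9 of 9 (median 2.24; Msln at 2.24, SE 0.86, and Gpm6a at 3.09, SE 1.24). Extracellular matrix genes were higher in 27 of 29 (median 0.82), with Thbs1, encoding thrombospondin, at 3.59 (SE 0.66) and Timp1 at 1.02 (SE 0.31). Cell cycle genes were higher in 22 of 25 (median 0.47), with the ribonucleotide reductase gene Rrm2 at 1.06 (SE 0.20) and Mki67 at 1.44 (SE 0.46). Rrm2 depended on the probe set: the others gave 0.51 and 0.15, and its value was as low as 0.39 when a knockout array was left out, because the probe set giving 0.51 then had the highest mean. Mki67 was 0.89 without the library labelled wildtype adipose replicate 3, and Gpm6a 4.65 without wildtype replicate 1. All 8 lists were called by camera with the preset correlation, at adjusted p between 4.8e-13 for the respiratory chain and 0.0066 for fatty acid synthesis. None held: each had adjusted p = 0.66 with an estimated correlation. Adjusted over the list alone, all 15 brown-fat genes passed, as did Thbs1 (adjusted p = 0.036) and Rrm2 (adjusted p = 0.032), and 0 genes of the other 5 lists passed. Without both libraries whose Terf2ip level opposed their label, the call ended for fatty acid synthesis (adjusted p = 0.40) and for extracellular matrix (adjusted p = 0.085). The means of glycolysis (-0.34), cell cycle (0.29) and mesothelium (1.44) were then also smaller by more than 1.5 times, with calls that held; this pair was chosen after seeing the data. The fatty acid synthesis call also ended without wildtype adipose replicate 2 (adjusted p = 0.10) and without the library labelled knockout adipose replicate 3 (adjusted p = 0.13). Without the library labelled wildtype adipose replicate 3 alone, the mean log2 fold change was 0.37 in place of 0.89 for extracellular matrix, -0.37 in place of -0.56 for glycolysis and -0.34 in place of -0.54 for the respiratory chain. Without wildtype adipose replicate 1 it was 1.43 for extracellular matrix and -0.42 in place of -0.27 for fatty acid synthesis.

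The wildtype adipose libraries differed among themselves in these same programmes. Brown-fat genes had list means of 9.03 in wildtype replicate 1, 11.7 in replicate 2 and 12.1 in the library labelled wildtype adipose replicate 3, and of 7.48, 8.01 and 8.39 in the 3 knockout libraries. Mesothelial genes read 9.54 in wildtype replicate 1, close to the knockout values of 9.25 to 9.93, and 6.31 and 6.15 in the other 2 wildtype libraries. The respiratory chain mean of wildtype replicate 1 was 12.66, against 12.57 to 12.70 in the knockout libraries and 13.31 and 13.59 in the other 2 wildtype libraries. Skeletal muscle genes did not follow the labels, with list means of 11.1 in wildtype replicate 1, 9.86 in the library labelled wildtype replicate 3 and 11.3 in the library labelled knockout replicate 3, against 6.76 to 6.79 in the other 3 arrays. The 3' minus 5' control signal of Actb, a sign of RNA quality, was 0.69 in wildtype replicate 1 and 1.15 to 1.54 in the other 5 arrays. That of Gapdh was -0.0090 in wildtype replicate 1 and -0.12 in the library labelled wildtype replicate 3, and 0.15 to 0.66 in the other 4.

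**Figure D2:**
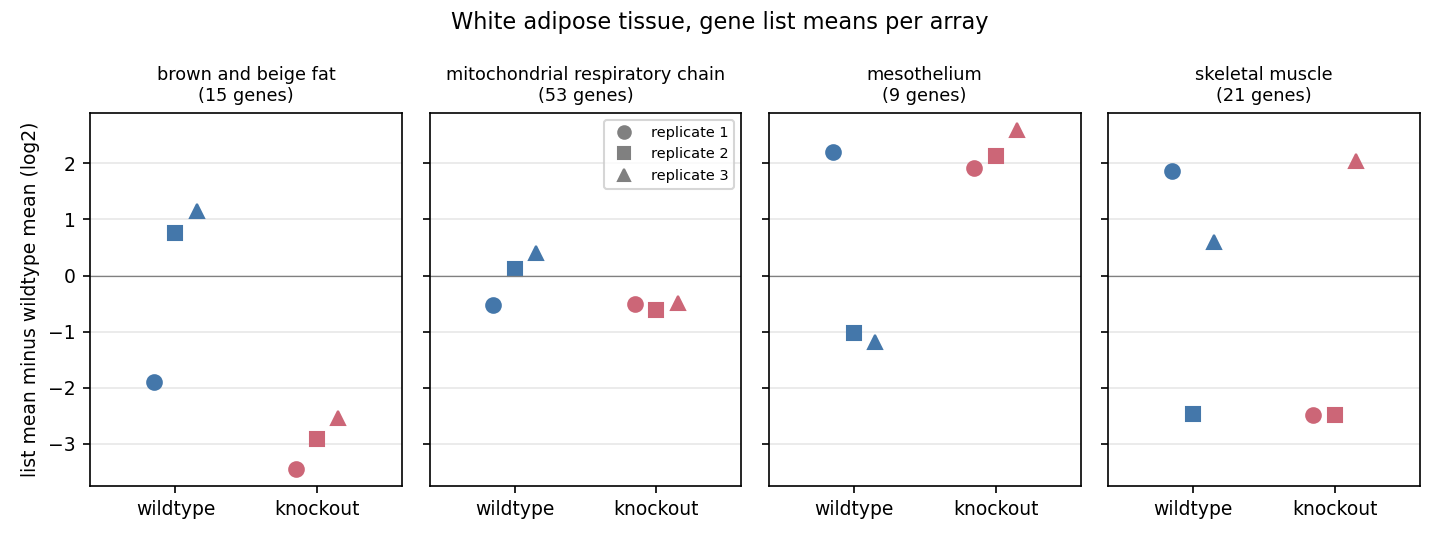
Mean log2 value of 4 gene lists in each white adipose tissue array, minus the mean of the 3 wildtype arrays, by genotype label, with symbols for the replicate number. Wildtype replicate 1 lies with the knockout libraries for mesothelial genes (2.20 against 1.92 to 2.60) and respiratory chain genes, and above them for brown-fat genes (-1.90 against -3.45 to -2.54).

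Single genes of adipose tissue did not pass with all 6 arrays. Of 12848 genes, 0 had an adjusted p under 0.05 in limma and 1516 an unadjusted p under 0.05 (935 higher, 581 lower), where 642 would be expected by chance. This count rested on single arrays: it was 4403 without wildtype replicate 1, and 715 and 543 without knockout replicates 1 and 2. In 2505 genes (19.5%) the groups did not overlap, where chance gives 10%. The smallest p belonged to Pgr, the progesterone receptor gene, at 9.13 ± 0.23 in the knockout and 5.86 ± 0.47 in the wildtype libraries, a log2 fold change of 3.27 (SE 0.26, adjusted p = 0.11). This rested on 1 of 3 Pgr probe sets: the other 2, both under the filter on low values, read 5.51 against 5.04 and 5.52 against 5.64 in knockout and wildtype. The wildtype level lay under the lowest 25th percentile of the arrays, 5.90, so the fold change was taken against a signal near background. The kinase gene Dapk1 followed at 1.54 (SE 0.16), with the AP-1 gene Fosl2 at 1.71 (SE 0.20), Greb1, a gene induced by oestrogen, at 1.32 (SE 0.16), the integrin gene Itgb8 at 1.64 (SE 0.23) and Prr15 at 1.49 (SE 0.20). The circadian output factor gene Hlf, at -1.43 (SE 0.19), and the taurine transporter gene Slc6a6, at -1.12 (SE 0.16), were lower, with Cyp27a1, Ackr3 and Carhsp1 between -0.86 and -0.74, and Dtx4, Gm19531, Slc7a8, Bace2 and Adamts3 higher by 0.92 to 1.07. Without wildtype adipose replicate 1, 2087 genes passed, 1235 higher and 852 lower in the knockout libraries, of which 2079 had the same sign with all arrays. Among them were 9 mesothelial, 14 brown-fat and 39 respiratory chain genes. Replicate 1 was the only wildtype library with mesothelial genes near the knockout values. Without it, differences in tissue content between the libraries and differences by genotype cannot be told apart. With all 21 arrays in 1 fit, 200 genes passed, 98 higher and 102 lower, and with array weights 1738 passed.

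Camera called none of the other lists in adipose tissue with all 6 arrays and the settings used here. Under 17 alternatives it called 8 to 11 lists, with hepatocyte genes called in 8 of the 17, and Hox, skeletal muscle and unfolded protein response genes in 5 each. Fry's test for change in either direction called the circadian clock list (adjusted p = 0.015), where 13 of 21 genes were lower and Hlf, Usp2 and Ciart passed when adjusted over the list alone (-1.43, -0.63 and -0.67), and the ovary and uterus list (adjusted p = 0.012), where 6 of 9 were lower and Pgr passed when adjusted over the list alone. The mean of the ovary and uterus list was 7.39 to 7.44 in the knockout and 6.64 to 7.17 in the wildtype libraries, but without Pgr it was 7.19 to 7.20 and 6.76 to 7.27, with overlap. The epithelial list mean was 7.73 to 7.95 in the knockout and 6.79 to 7.56 in the wildtype libraries. Keratin genes of simple epithelia were higher, Krt18 at 1.20 (SE 0.29), Krt8 at 1.87 (SE 0.55) and Krt7 at 1.87 (SE 0.62), and these 3 passed when adjusted over the list alone, while 4 of the 6 epithelial genes were higher (adjusted p = 0.17). Hox genes, which mark body position, were higher in 15 of 22 (adjusted p = 0.073), with Hoxc10 at 3.07 (SE 0.91) and Hoxa10 at 2.09 (SE 0.65). Lep, the leptin gene, was at 1.99 (SE 1.01). Slc2a4, the insulin-responsive glucose transporter gene, was at -0.97 (SE 0.24), in lists of adipocyte identity (14 of 19 higher, adjusted p = 0.20) and of insulin signalling (14 of 21 higher, adjusted p = 0.59). Macrophage genes were higher in 24 of 31 (adjusted p = 0.26), skeletal muscle genes lower in 20 of 21 (adjusted p = 0.079) and hepatocyte genes lower in 8 of 8 (adjusted p = 0.052). Camera called the macrophage list without wildtype adipose replicate 1 (mean log2 fold change 1.04, adjusted p = 9.3e-06) and with array weights (0.58, adjusted p = 0.0096).

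The knockout effects of the 2 tissues were compared directly through the interaction of tissue and genotype. Of 13116 genes, 1 passed: the effect on Pgr was 3.27 in adipose tissue and -0.13 in liver, a difference of 3.39 (SE 0.29, limma adjusted p = 0.0016). Pgr read 5.80 and 5.93 in knockout and wildtype liver, under the filter level of 6.50 that its mean over both tissues passed, so a fall in liver could not have been seen. The next genes did not pass (adjusted p = 0.44 each). They were Dapk1, Rras2, Bace2, Dtx4, Aff3 and Lnx2, whose adipose effect exceeded that in liver by 0.91 to 2.21, and Slc6a6, where the difference was -1.01. An unadjusted p under 0.05 was reached by 1334 genes, or 850 to 3875 without single arrays. The number that passed was 1921 without wildtype adipose replicate 1, 2 without the library labelled wildtype adipose replicate 3, and 0 when any 1 knockout adipose array was left out, because the mean of Pgr then lay under the filter on low values.

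In MEF, the knockout cells carried more interferon-induced and extracellular matrix RNA than the wildtype cells. All 28 measured interferon response genes were higher, with a median log2 fold change of 1.20. The antiviral genes Mx1, Mx2 and Oas2 differed by 1.74 (SE 0.46), 0.96 (SE 0.29) and 0.89 (SE 0.27). Of 29 extracellular matrix genes 26 were higher (median 0.84), among them the collagen genes Col1a1 at 2.20 (SE 0.56), Col4a1 at 1.21 (SE 0.33), Col4a2 at 1.11 (SE 0.24) and Col5a2 at 1.09 (SE 0.25). Cell cycle genes were lower in 26 of 31 (median -0.24; Cdt1, which licenses replication origins, at -0.42, SE 0.15), and insulin and IGF signalling genes were higher in 14 of 21 (median 0.15), led by the growth factor gene Igf1 at 8.82 ± 0.17 against 6.84 ± 0.62 in wildtype MEF, a log2 fold change of 1.98 (SE 0.30).

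Camera with the preset correlation called these lists in MEF at adjusted p = 1.6e-23 for interferon response, 4.3e-17 for extracellular matrix, 1.1e-05 for cell cycle and 0.022 for insulin and IGF signalling. The calls were lost with an estimated correlation, at adjusted p = 0.27, 0.094, 0.55 and 0.56 in the same order, and with fry's directional test. Adjusted over the list alone, 0 interferon genes, 4 extracellular matrix genes and Igf1 (adjusted p = 0.0028) passed. With the replicate number as a block, 26 interferon and 13 extracellular matrix genes passed over the list alone. The interferon mean was 0.74 without wildtype MEF replicate 1, in place of 1.24. The cell cycle call ended without wildtype MEF replicate 1 (adjusted p = 0.13), as did the insulin and IGF call (adjusted p = 0.13), which also ended without the library labelled wildtype MEF replicate 2 (adjusted p = 0.22) and without knockout MEF replicate 3 (adjusted p = 0.30).

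A further 6 lists were called in knockout against wildtype MEF with the preset correlation, and each lost its call without at least 1 array. Fatty acid oxidation (28 of 36 higher, adjusted p = 0.038), fatty acid and triglyceride synthesis (18 of 24, adjusted p = 0.012), cholesterol synthesis (18 of 20, adjusted p = 0.0091), the respiratory chain (44 of 53, adjusted p = 0.0091) and the unfolded protein response (18 of 21, adjusted p = 0.015) were higher. Immediate early and heat shock genes were lower in 13 of 19 (adjusted p = 0.0091; Klf4 at -0.67, SE 0.28, or -0.41 without the library labelled wildtype MEF replicate 2). Their adjusted p lay between 0.53 and 0.74 with an estimated correlation. Without wildtype MEF replicate 1 the calls ended for fatty acid oxidation (adjusted p = 0.22), fatty acid synthesis (0.13) and cholesterol synthesis (0.27), and the respiratory chain mean turned from 0.12 to -0.039. Without the library labelled wildtype MEF replicate 2 they ended for fatty acid oxidation (0.17), fatty acid synthesis (0.28), cholesterol synthesis (0.11) and the unfolded protein response (0.16), and without the library labelled wildtype MEF replicate 3 for the unfolded protein response (0.094) and immediate early genes (0.36). Without knockout MEF replicate 1 they ended for fatty acid oxidation, fatty acid synthesis and cholesterol synthesis (0.13 each) and immediate early genes (0.10), without replicate 2 for fatty acid oxidation (0.17), immediate early genes (0.21) and the unfolded protein response (0.090), and without replicate 3 for the respiratory chain (0.10). Without all 3 MEF libraries numbered 1, a choice made after seeing the data, the mean log2 fold change turned from 0.43 to -0.010 for cholesterol synthesis and from 0.12 to -0.014 for the respiratory chain. Other means moved by more than 1.5 times with their call kept: cholesterol and fatty acid synthesis to 0.72 and 0.43 without the library labelled wildtype MEF replicate 3, the respiratory chain to 0.21 and immediate early genes to -0.43 without the library labelled wildtype MEF replicate 2, and immediate early genes to -0.48 without knockout MEF replicate 3.

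Of 12816 genes, 0 passed in knockout against wildtype MEF in limma, and 443 had an unadjusted p under 0.05 (301 higher, 142 lower), where 641 would be expected by chance for independent arrays. The latter count was 1013 without the library labelled wildtype MEF replicate 3 and 218 without knockout replicate 2. With the replicate block 0 passed and 1139 had an unadjusted p under 0.05 (655 higher, 484 lower). The 16 genes with the smallest p, none past the threshold, were Igf1 and others that were mostly higher in knockout MEF: the hedgehog co-receptor gene Boc at 0.83 (SE 0.15), the protease-like gene Prss35 at 1.83 (SE 0.34), Tgfb2, encoding a transforming growth factor, at 1.59 (SE 0.34), the Notch ligand gene Jag1 at 1.35 (SE 0.29), the amino acid transporter gene Slc7a5 at 1.07 (SE 0.21), Pgm5 at 1.20 (SE 0.24) and the limb factor gene Tbx4 at 1.16 (SE 0.24). Ctla2a, Adamts12, Ccn4, Cth, Col4a2 and Col5a2 were higher by 0.71 to 2.06. The mitochondrial fission factor gene Mff, at -1.11 (SE 0.21), and Rragd, encoding a GTPase of the mTORC1 pathway, at -1.12 (SE 0.21), were lower.

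MEF that expressed Rap1 I312R addressed whether the mutant protein changes what is seen in knockout cells. Compared with knockout MEF, all 28 interferon response genes were lower in I312R MEF (median -1.23), with Mx1 at -2.03 (SE 0.46), Oas2 at -1.22 (SE 0.27) and Stat2 at -1.14 (SE 0.29). Extracellular matrix genes were lower in 26 of 29 (median -0.73; Col1a1 at -2.45, SE 0.56, and Col4a2 at -1.47, SE 0.24). Igf1 differed by -1.73 (SE 0.30). Cell cycle genes were higher in 27 of 31 (median 0.18; Rrm2 at 1.00, SE 0.34).

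Camera with the preset correlation called the interferon list (adjusted p = 2.4e-33), the extracellular matrix list (adjusted p = 5.2e-18) and the cell cycle list (adjusted p = 0.00021) between I312R and knockout MEF. With an estimated correlation the calls were lost, at adjusted p = 0.13, 0.082 and 0.55 with an estimated correlation. Adjusted over the list alone, 19 interferon and 10 extracellular matrix genes passed, and 25 and 14 with the replicate block. The block also called glycolysis, with 14 of 16 lower (adjusted p = 0.0040 in place of 0.074; adjusted p = 0.65 with an estimated correlation). The cell cycle call ended without knockout MEF replicate 2 (adjusted p = 0.063). The other 6 lists called here, each with a call that ended without at least 1 array, were insulin and IGF signalling (15 of 21 lower, adjusted p = 0.0030), fatty acid and triglyceride synthesis (17 of 24 lower, adjusted p = 0.0030), cholesterol synthesis (19 of 20 lower, adjusted p = 0.029), p53 targets (18 of 20 higher, adjusted p = 0.0030), shelterin and telomerase genes (14 of 17 higher, adjusted p = 0.019) and immediate early genes (14 of 19 higher, adjusted p = 0.018). These 6 had adjusted p between 0.55 and 0.75 with an estimated correlation. Without knockout MEF replicate 1 the calls ended for fatty acid synthesis (adjusted p = 0.058), cholesterol synthesis (0.29), p53 targets and shelterin genes (0.060 each) and immediate early genes (0.12), without replicate 2 for immediate early genes (0.38), and without replicate 3 for insulin and IGF signalling (0.075) and p53 targets (0.061). Without I312R MEF replicate 1 they ended for insulin and IGF signalling and shelterin genes (0.052 each), fatty acid synthesis (0.071) and immediate early genes (0.12), and the cholesterol mean turned from -0.31 to 0.12. Without I312R replicate 2 they ended for cholesterol synthesis (0.31) and p53 targets (0.081), and without replicate 3 for shelterin and immediate early genes (0.073 each). The mean was -0.81 for cholesterol and -0.41 for fatty acid synthesis without I312R replicate 3, and 0.47 for immediate early genes without knockout replicate 3, with the call kept.

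**Figure D3:**
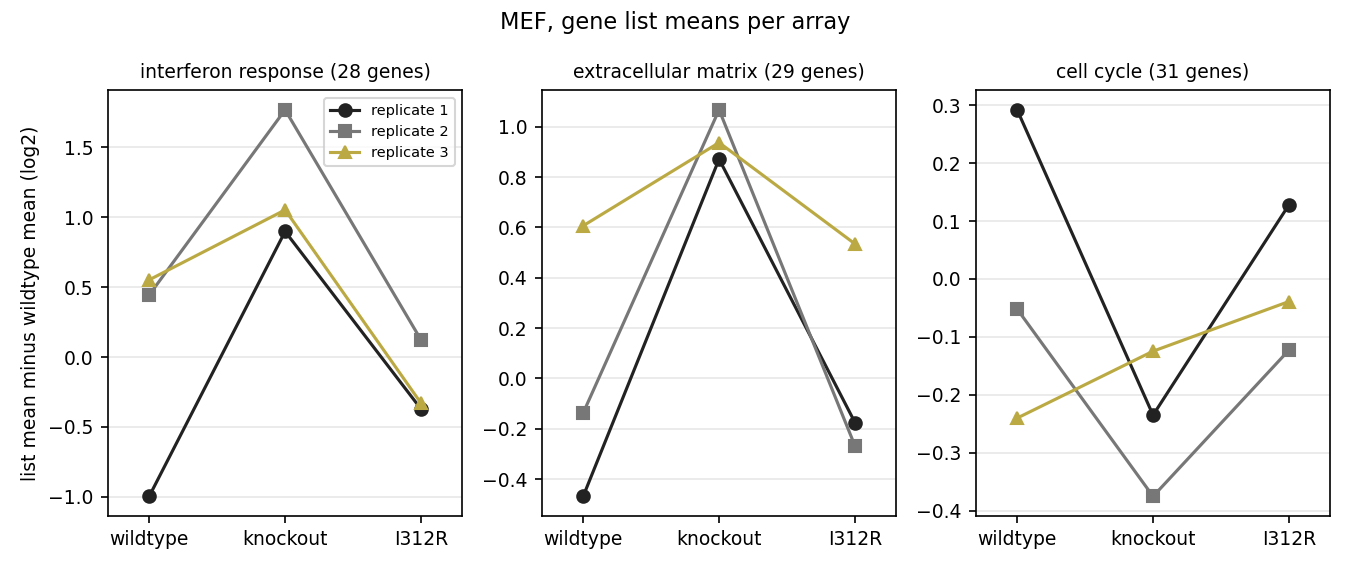
Mean log2 value of 3 gene lists in each MEF array, minus the mean of the 3 wildtype arrays, with lines joining arrays of equal replicate number. The interferon means of the knockout arrays (0.90 to 1.77) lie above those of the wildtype (up to 0.55) and I312R arrays (-0.37 to 0.12).

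No single gene passed between I312R and knockout MEF: 0 of 12816 in limma, with 501 at an unadjusted p under 0.05 (198 higher, 303 lower), or 284 to 733 without single arrays. With the replicate block 0 passed and 1292 had an unadjusted p under 0.05, of which more were higher than lower (686 and 606), and with array weights 592 genes passed, 204 higher and 388 lower. Among the 16 genes with the smallest p, none past the threshold, Boc, Prss35, Pgm5, Tgfb2, Igf1, Col4a1, Col4a2, the morphogen gene Bmp4, Bicc1, the DNA methyltransferase gene Dnmt3a, Chst15 and the interferon-induced GTPase gene Ifi47 were lower by -2.44 to -0.70. Mff at 1.27 (SE 0.21), the integrin-linked gene Parvb at 1.30 (SE 0.25), the transporter gene Slco4a1 at 1.74 (SE 0.35) and Ramp3 at 1.70 (SE 0.34) were higher.

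I312R MEF and wildtype MEF were compared last. Respiratory chain genes were higher in 50 of 53 by a median of 0.14 (Cox5a at 0.23, SE 0.15), p53 targets in 17 of 20 by a median of 0.35 (Ccng1 at 0.83, SE 0.59), unfolded protein response genes in 19 of 21 (Manf at 0.43, SE 0.22) and shelterin and telomerase genes in 14 of 17 (Dkc1, encoding dyskerin, at 0.56, SE 0.28). Without single arrays Ccng1 ranged from 0.22 to 1.47, Manf from 0.24 to 0.67 and Dkc1 from 0.30 to 0.90, each lowest without wildtype replicate 1 and highest without the library labelled wildtype replicate 2, and Cox5a was 0.11 without the library labelled wildtype replicate 3. Interferon genes were lower in 22 of 28 (median -0.29), glycolysis genes in 13 of 16 and NF-kB targets in 16 of 24. Camera called these 7 lists with the preset correlation at adjusted p between 8.3e-05 and 0.046, and each lost its call, at adjusted p = 0.97 with an estimated correlation, and without at least 1 array. With the replicate block the calls for NF-kB targets (adjusted p = 0.098) and shelterin genes (adjusted p = 0.059) were also lost. Without wildtype MEF replicate 1 the mean log2 fold change turned from -0.21 to 0.27 for glycolysis, from 0.14 to -0.02 for the respiratory chain and from -0.17 to 0.13 for NF-kB targets. The interferon mean turned from -0.19 to 0.029 and 0.083 without the libraries labelled wildtype MEF replicates 2 and 3, and was -0.69 without wildtype replicate 1. Calls for p53 targets ended without wildtype replicate 1 (adjusted p = 0.097), the library labelled wildtype replicate 3 (0.67), I312R replicate 1 (0.11) and I312R replicate 2 (0.46), with a mean of 0.70 in place of 0.36 without the library labelled wildtype replicate 2. The unfolded protein response call ended without the libraries labelled wildtype replicates 2 and 3 (0.37 and 0.11) and without I312R replicates 1 and 3 (0.11 and 0.38), and the shelterin call without wildtype replicate 1 (0.054), the library labelled wildtype replicate 3 (0.47) and I312R replicates 1 and 3 (0.11 and 0.078). Without I312R replicate 3 the interferon and respiratory chain calls ended as well (0.098 each), glycolysis turned to 0.069 without I312R replicate 2, and NF-kB targets ended without the library labelled wildtype replicate 3 (0.12) and I312R replicates 2 and 3 (0.71 and 0.096). Glycolysis also ended without the library labelled wildtype replicate 3 (0.086) and I312R replicate 3 (0.68), and its mean was -0.64 without I312R replicate 1 and -0.56 without the library labelled wildtype replicate 2.

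Of 12816 genes, 0 passed between I312R and wildtype MEF in limma and 26 had an unadjusted p under 0.05. By chance 641 would be expected for independent arrays, which the paired MEF arrays were not. The count was 231 with the replicate block and 545 (408 higher) without the library labelled wildtype MEF replicate 2. The smallest p belonged to Ushbp1 at 0.43 (SE 0.12). Itih2, Hfe, Hdac8 and Fbxw4 were lower by -0.52 to -0.31, and Bcl6b, Rad1, C330018D20Rik, Cd34, Zfp239, Ramp3, Zfp105, Dbnl, Tmem33, Gspt1 and Wdr77 were higher by 0.35 to 1.09, none past the threshold. Without single arrays some of these moved by more than 1.5 times: Zfp105, the highest, to 0.50 and Tmem33 to 0.24 without wildtype replicate 1, Ramp3 to 0.52 without the library labelled wildtype replicate 3 and to 1.29 without the one labelled wildtype replicate 2, and Cd34 to 0.57 and Fbxw4 to -0.27 without I312R replicate 1.

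The place of I312R MEF between the other MEF groups was read from fold changes across genes, which are not independent replicates. Knockout and I312R fold changes against the same wildtype arrays correlated at r = 0.32, below the r = 0.50 that the shared arrays gave in simulations with no effect. The covariance was 0.021 against a simulated 0.056, or 0.026 when the simulation used the spread left after the replicate block. Knockout against wildtype and I312R against knockout, which share the knockout arrays, correlated at r = -0.81 against a simulated -0.50, with a covariance of -0.087 against a simulated -0.055, or -0.026 with the block. Single arrays moved the first of these: r was 0.62 and 0.70 without the libraries labelled wildtype MEF replicates 2 and 3 (simulated 0.60 each), 0.17 without wildtype replicate 1 (simulated 0.60) and 0.014 without I312R replicate 3 (simulated 0.44). As no gene passed, overlaps were counted at an unadjusted p under 0.05. Of 301 genes higher and 142 lower in knockout than wildtype MEF, 190 and 67 had the opposite difference in I312R against knockout MEF, which shares the knockout arrays. In I312R against wildtype MEF only 19 and 7 genes reached this p, of which 2 and 0 had the same direction. As the lists differed in length from each other and from the simulated ones, the 500 genes with the smallest p in each comparison were compared as well, a choice made after the results were seen. Of these, 272 had the opposite difference in knockout against wildtype and I312R against knockout MEF, where 100 simulations of unchanged groups gave 97 to 145, and 38 had the same direction in knockout and I312R against wildtype MEF, where they gave 98 to 143. With the replicate block the counts were 274 (simulated 106 to 157) and 25 (simulated 109 to 147). The simulations drew genes as independent, so their ranges are narrower than those of real arrays. They also drew arrays as independent. Equally numbered I312R and wildtype arrays deviated together most, at 0.72 to 0.79. Knockout arrays did so less, at 0.39 to 0.54 with wildtype and 0.24 to 0.47 with I312R. Such unequal pairing alone lowers the first correlation, makes the second more negative and shifts the overlaps likewise. The block, which treats the groups alike, does not remove it. The distances from the simulations therefore cannot show an effect of genotype.

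**Figure D4:**
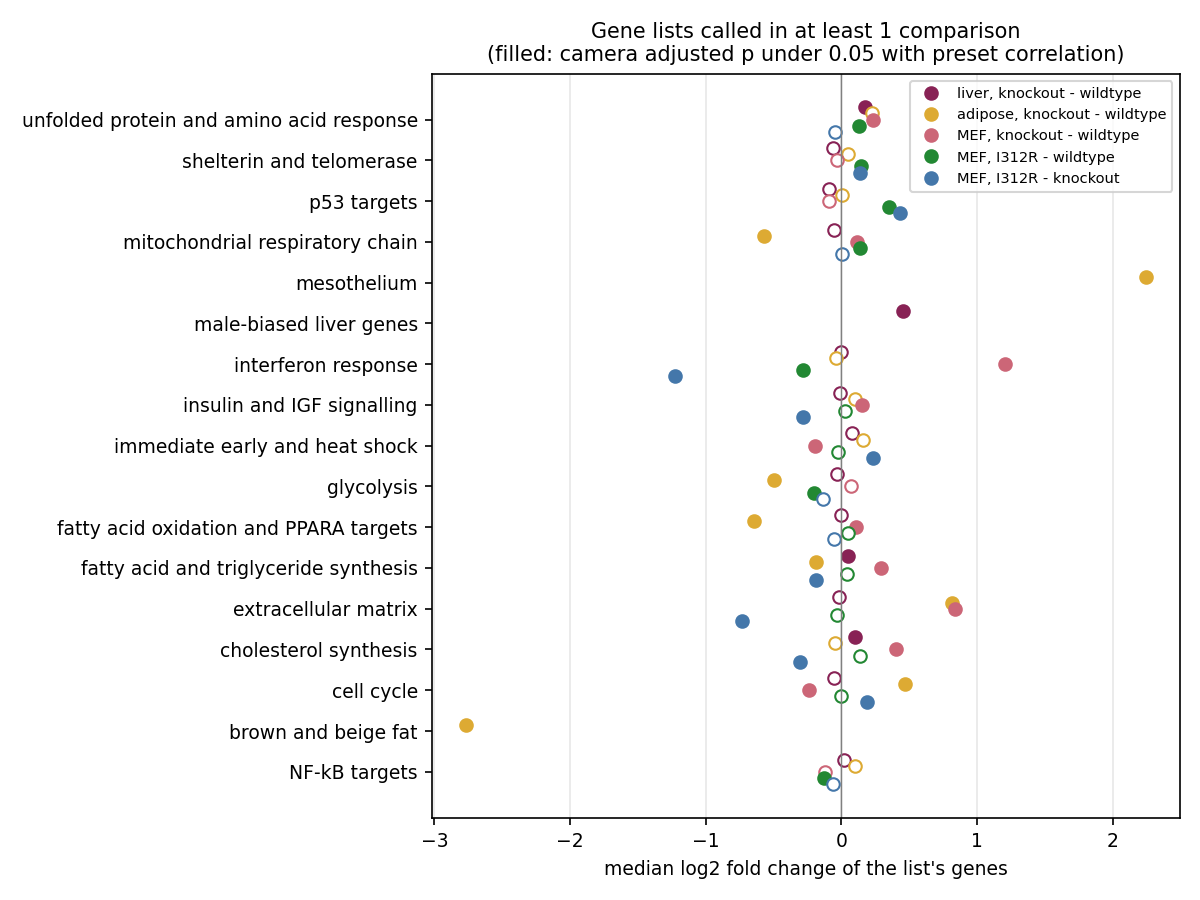
Median log2 fold change of the genes of each list called in at least 1 of the 5 comparisons, with 1 colour per comparison and filled points where camera's adjusted p was under 0.05 with the preset correlation. Interferon response lies at 1.20 in knockout against wildtype MEF and at -1.23 in I312R against knockout MEF, and brown-fat genes lie at -2.77 in adipose tissue.

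Genes that neighbour Terf2ip on its chromosome were counted separately. Within 10 Mb, 0 of 170 tested genes in liver, 0 of 166 in adipose tissue and 0 of 163 in MEF passed in knockout against wildtype in limma, and as 0 passed elsewhere the shares could not differ. An unadjusted p under 0.01 was reached by 1, 4 and 1 of these genes (Fisher's exact test, two-sided, p = 0.48, 0.56 and 0.61). Probe sets without a gene name, tested separately, gave 0 calls in each of the 5 comparisons, from 3992 in liver, 4114 in adipose tissue and 3920 in MEF, with 93 in liver, 407 in adipose tissue and 71, 13 and 79 in MEF (knockout against wildtype, I312R against wildtype, I312R against knockout) at an unadjusted p under 0.05 in limma.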

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

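All tests of explanations in this part were chosen after the result was seen, and only the counts over other splits of the arrays were planned. Pgr stood out because its knockout effect differed between the tissues, by 3.39 on the log2 scale (adipose minus liver, limma adjusted p = 0.0016, between 5.5e-07 and 0.049 over the alternatives that tested it). All 3 knockout adipose arrays read 8.96 to 9.39 and all 3 wildtype adipose arrays 5.47 to 6.39, on 1 of 3 probe sets, and the wildtype and liver levels were near background. The epithelial list mean also separated the adipose groups (7.73 to 7.95 against 6.79 to 7.56), but camera did not call that list with all arrays and the settings used here. The ovary and uterus mean without Pgr did not separate them (7.19 to 7.20 against 6.76 to 7.27). Of 100 drawn splits of the arrays within both tissues, from 200 possible, 30 gave at least 1 gene, the real one included. The highest other split gave 26. The possible splits include ones that regroup only the livers and keep the adipose groups, and with them the difference in Pgr. The count therefore cannot decide whether the 1 gene arose by chance, which is not excluded.

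In adipose tissue, brown-fat genes were lower and mesothelial genes higher in the knockout libraries. Fat of different depots, or brown fat in some dissections, is a candidate explanation: the mesothelial mean spanned 3.39 log2 units among the wildtype libraries, more than the 2.22 between the genotype means, and only 0.68 among the knockout libraries. The wildtype span came from wildtype replicate 1, whose place near the knockout libraries was already seen, so it is no separate support. Muscle in the dissections is argued against, since among the 3 libraries poor in muscle RNA the 2 knockouts lay at a mean of -3.94 in brown-fat genes relative to wildtype replicate 2, and the library labelled knockout replicate 3, rich in muscle RNA and with a Terf2ip level that opposes its label, lay at -3.29. Loss of Rap1 within one depot cannot be told apart from these, because only wildtype replicate 1 carried mesothelial genes, at 1.07 above the knockout mean in brown-fat genes. The depot of each animal is not given in the sources used here.

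The Terf2ip level opposed the label in several libraries. In liver the signal followed the genotype, with a difference of -0.82 and no overlap. That cannot decide whether the probe set reads the deleted part, since a transcript without that part could also fall in amount. Muscle RNA is argued against for the library labelled knockout adipose replicate 3, since the wildtype adipose library richest in muscle RNA differed from the poorest by -0.25 in Terf2ip, while that library exceeded knockout replicates 1 and 2 by 1.52. A wrong label for that library may account for the 1.52: its brown-fat mean of 8.39, and that of 12.1 in the library labelled wildtype adipose replicate 3, lay with their labels, but brown-fat genes may follow the depot, and because no gene is known to follow Rap1 here a wrong label and a true knockout cannot be told apart. For MEF the origin of the wildtype cells stays open as well.

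Interferon and extracellular matrix genes were higher in knockout MEF than in wildtype and I312R MEF. The libraries numbered 1, which hold the only female culture and the only wildtype MEF with high Terf2ip, are argued against as the whole cause: over the pairs numbered 2 and 3 the mean difference between knockout and wildtype was 0.91 for interferon and 0.77 for matrix genes, positive in both pairs. The pairs were uneven. Interferon genes differed by 1.89, 1.32 and 0.50 in pairs 1, 2 and 3, and matrix genes by 1.34, 1.20 and 0.33. Loss of Rap1 itself remains a possible explanation but was not separated from other differences between the cultures, because Terf2ip in pairs 2 and 3 differed by 0.084 (knockout minus wildtype) and the position of the probe sets is not given. The knockout group held cultures of both sexes, so it came from more than 1 embryo. Its female culture, replicate 1, cannot be the source of the I312R cultures, which had male markers. The culture line of each group is otherwise open, as is the vector, and neither was tested.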

How the results depend on the processing

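The alternatives were planned, except leaving out both adipose libraries whose Terf2ip opposed their label, or the 3 MEF libraries numbered 1, and counting overlaps with the replicate block or in lists of equal length, which were chosen after seeing the data. Leaving out the adipose pair gave 0 genes in adipose tissue and 2 in the interaction; leaving out the MEF libraries gave 0. The counts for liver, knockout against wildtype MEF and I312R against wildtype MEF stayed at 0 under all alternatives, without any single array included. In adipose tissue 200 genes passed with all 21 arrays in 1 fit, 1738 with array weights, and 0 to 2087 without single arrays, the highest without wildtype replicate 1. I312R against knockout MEF gave 592 genes with array weights. The interaction gave 2722 genes with array weights, 0 to 1921 without single arrays, and 0 with the 60th percentile filter, the mean of probe sets or all arrays in 1 fit, because the mean of Pgr then lay under the filter. Array weights stopped before their tolerance in 2 of 6 fits, those of adipose tissue and the interaction. The cause of the other moves was not tested. A pseudocount was not run, as the values were already log2. The replicate block gave 0 genes in each of the 5 comparisons. In the interaction the block took equal numbers within a genotype as 1 animal across both tissues, which the labels do not state. It gave 1 gene there, Pgr (limma adjusted p = 0.049). The deviations of equally numbered liver and adipose arrays correlated at only -0.081 to 0.048 across genes. The block of the 5 comparisons raised liver genes at an unadjusted p under 0.05 from 316 to 829 and left adipose tissue at 1490. Adjusted over all genes, it changed no call of a gene. Adjusted over a list alone, more interferon and extracellular matrix genes passed with it in both comparisons with knockout MEF. Over all alternatives camera called 5 to 10 lists in knockout against wildtype MEF, 1 to 8 in I312R against wildtype MEF and 5 to 13 in I312R against knockout MEF. The block added the respiratory chain in liver (47 of 53 lower, adjusted p = 0.047; 0.85 with an estimated correlation) and, in adipose tissue, skeletal muscle (0.022), hepatocyte (0.019) and unfolded protein response genes (0.048; 0.69 to 0.91 with an estimated correlation).

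The correlation of knockout and I312R fold changes was 0.014 to 0.70 without single arrays. Near Terf2ip, Fisher's exact p at an unadjusted p under 0.01 lay between 0.21 and 1 in windows of 5 and 20 Mb.

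Of the named genes' values under alternatives, 3983 kept their direction and side of the threshold, 145 passed it and 17 reversed; of the lists' values, 569 were the same, 164 lost the call and 11 reversed. In the reversals the cause was not tested. Cdc20 in adipose tissue was -0.057 after quantile normalization. With array weights Terf2ip was 0.043 in knockout and 0.14 in I312R against wildtype MEF. Without the MEF libraries numbered 1, knockout against wildtype gave -0.010 for cholesterol synthesis, -0.014 for the respiratory chain and 0.084 for Terf2ip, I312R against wildtype gave 0.22 for Terf2ip, and I312R against knockout gave 0.23 for cholesterol synthesis, 0.096 for Hmgcs1, 0.016 for Cyp51 and 0.23 for Fdps.

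Without single arrays, Terf2ip ranged from -0.57 to 0.23 in adipose tissue, from -0.48 to 0.075 in knockout and from -0.30 to 0.26 in I312R against wildtype MEF. In knockout against wildtype MEF the respiratory chain ranged from -0.039 to 0.21 and Irs1 from -0.059 to 1.01. In I312R against wildtype MEF glycolysis ranged from -0.64 to 0.27, interferon response from -0.69 to 0.083, the respiratory chain from -0.020 to 0.23, NF-kB targets from -0.35 to 0.13, Hk2 from -0.86 to 0.24, Hk1 from -1.05 to 0.13 and Pfkfb3 from -1.08 to 0.42. Cholesterol synthesis in I312R against knockout MEF ranged from -0.81 to 0.12. Signal over background limits what arrays show for weakly expressed genes.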

Other observations

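Genes of the circadian clock list were not called in liver (11 of 21 higher, adjusted p = 0.53), with Arntl, the clock activator gene, at -0.68 (SE 0.24) and Nfil3 at -0.49 (SE 0.21). Xenobiotic metabolism genes were lower in 17 of 29 (adjusted p = 0.31), among them Cyp2b10, a target of the receptor CAR, at -1.01 (SE 0.32), and in gluconeogenesis (7 of 13 lower, adjusted p = 0.53) the coactivator gene Ppargc1a was at -0.78 (SE 0.28). Camera did call the clock list without wildtype liver replicate 3 (mean -0.23, adjusted p = 0.00026) and without knockout liver replicate 2 (mean -0.18, adjusted p = 0.032). Xenobiotic metabolism and gluconeogenesis were each called in 2 of 16 alternatives, with means below 0.

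The counts of genes and lists called over other splits were planned, and the count at an unadjusted p over splits was added after the results were seen. The livers carried differences between arrays that did not follow the genotype. The split that set knockout replicates 1 and 2 with wildtype replicate 2 against the other 3 livers gave 2662 genes at an unadjusted p under 0.05, against 316 for the genotype. It kept the livers numbered 2 on the same side, and likewise those numbered 3. The highest other splits gave 1502 against 1516 in adipose tissue, 1780 against 443 in knockout against wildtype MEF, 2228 against 26 in I312R against wildtype MEF and 614 against 501 in I312R against knockout MEF. Among splits that part all equally numbered arrays, the highest others gave 329 in liver and 1160 in adipose tissue. In the MEF comparisons they gave 358, 41 and 338.

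The 10 splits of 6 arrays are too few for a share under 0.05. The real splits gave 0 genes in each of the 5 comparisons, so that all 10 splits gave as many, and the highest other split gave 8 in liver, 20 in adipose tissue and 0 in each MEF comparison. The split with 20 set knockout adipose replicates 1 and 2 and wildtype replicate 2, all poor in skeletal muscle RNA, against the other libraries. Its grouping was thus that of muscle RNA and not of genotype. The split with 8 set knockout liver replicates 1 and 3 and wildtype replicate 3 against the other livers. It too kept the livers numbered 2 on the same side, and likewise those numbered 3, and its cause was not tested. For lists, the real splits called 4 in liver, 8 in adipose tissue, 10 in knockout against wildtype MEF, 7 in I312R against wildtype MEF and 9 in I312R against knockout MEF, and the highest other splits called 9, 11, 10, 9 and 11. Splits with as many numbered 9, 8, 2, 5 and 3 in the same order. In MEF, where the numbers pair the arrays, the other 3 splits that part all pairs called at most 9, 4 and 10 lists.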
